A study of Mus musculus with 19 samples.

How the data were processed

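Lung RNA was sequenced from 19 C57BL/6J mouse offspring. Their dams drank water with 200 mg/L nicotine and 2% saccharin, or with 2% saccharin alone, from mating through gestation and lactation, per the labels' protocols. Lungs were snap frozen, RNA was purified with a Macherey-Nagel kit and libraries were made with the Illumina TruSeq RNA kit, per the labels. The reads were single-end, 50 nt long and came from an Illumina HiSeq2500. Each mouse's age, agent and sex came from its labels. The extraction protocol shared by all samples gives only postnatal day 2, with 6 saccharin and 5 nicotine lungs, whereas the age field puts 8 mice at day 16. The age field was used, and this conflict was not resolved. Replicate numbers followed the order of the deposited records and only name mice.

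The authors deposited 1 table of raw read counts per Ensembl gene. The submitters' processing notes name CASAVA 1.8.2, STAR 2.4, featureCounts 1.4.6 and the GRCm38 build. The annotation release, the counting options and the strand setting are not given in the sources used here. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and counts of near-identical gene families are uncertain. The table held 21839 genes, of which 21628 matched GENCODE release M21 by identifier. The 211 others held 0.041% of all counts. GENCODE M21 gave symbols, coordinates, lengths and GC content, and may differ from the release used for counting. The table held 20838 protein-coding genes, 454 immunoglobulin and T cell receptor segments and 0 genes of the mitochondrial genome. Xist, Tsix, H19 and Meg3 were not analysed here. Total counts ran from 12976749 to 27302477 per mouse.

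Genes were kept by the filterByExpr function of edgeR with a minimum count of 10, which left 15143 genes. Libraries were scaled by TMM factors. The edgeR 4.0.16 quasi-likelihood F test with a robust prior was run in R 4.3.3 on 1 model of all 19 mice, with a term for each of the 4 age and agent groups and a term for sex. The common biological coefficient of variation was 24.1%, with 14 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene passed at an adjusted p under 0.05. All adjusted p-values of genes below are edgeR values unless another tool is named. Those with blocks of consecutive mouse numbers as a random effect are limma-voom values. Contrasts were nicotine against saccharin at each age, the difference of those contrasts, day 16 against day 2 in saccharin mice, and female against male. Values per mouse are CPM, counts scaled to a common library size by edgeR with TMM factors, and log2 CPM used a prior count of 2. SE stands for the standard error of a log2 fold change. The p-values treat offspring as independent, and the labels do not say which mice shared a dam.

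The design, the alternatives and 58 gene lists of cell types, other tissues, matrix, metabolism, stress and signalling were fixed before the data were examined. Lists with at least 5 tested genes entered camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 56 lists tested. Camera with a correlation estimated from the data, and fry, stood beside it. No list passed with an estimated correlation in any comparison. Counts of list members use the adjustment over all genes, and a further count uses values adjusted over the list alone.

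The rule for naming genes was also fixed. For the nicotine effect at each age and for development it took the 8 largest and 8 smallest log2 fold changes among passing genes. These needed an average log2 CPM above 1 and a symbol that was not a predicted, cloned or sex-linked marker gene. Up to 10 further list members of smallest adjusted p were added. If fewer than 5 genes passed, the 5 of smallest p were named as not passing. The difference between the ages took 5 genes per direction, of which 2 are not reported here, and sex took 6 sex markers. Eln, Col1a1, Pdgfra, Acta2, Sftpc, Ager, Vegfa, Mki67, Chrna3, Chrna5, Chrna7 and Chrnb4 were always given for the nicotine effect at each age and for development. Within a described list the 2 to 4 members of smallest adjusted p were named.

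The pipeline was tested on simulated counts with 100 genes changed at each fold size. With the day 2 groups, 84% of 2-fold and 98% of 4-fold changes were recovered among 15019 genes, with 11 false calls. With the day 16 groups the shares were 55% and 95% among 15018 genes, with 5 false calls. In a separate simulation an added length trend gave 724 and 150 calls, and 0 after the length and GC correction. That trend followed the same gene lengths that the correction fits, so its removal does not show how well the correction spares biology.

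The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample quality weights, no low-count filter, a CPM above 1 in at least 3 libraries, no sex term, no robust prior, an adjusted p under 0.1, a 2-fold minimum and leaving out each mouse. Others used mice of 1 age, females, or mice of 1 run of mouse numbers, and a term for the number run. Several alternatives were added after the data had been seen. They were a spline correction of each library for gene length and GC content with 4 degrees of freedom, blocks of consecutive mouse numbers as a random effect or as summed counts, and a changed sex label for nicotine day 16 replicate 2. The random-effect blocks were fitted by limma-voom without quality weights, and the block sums by edgeR without a sex term. Further ones left out sets of libraries. These were saccharin day 2 replicates 2 and 3 with nicotine day 2 replicate 3, and the 4 of the strongest length trend, saccharin day 2 replicates 2 and 3 and saccharin day 16 replicates 2 and 4. Others were 3 unusual libraries, saccharin day 2 replicates 2, 3 and 6, and the 2 with the highest skeletal muscle scores, nicotine day 2 replicate 3 and saccharin day 2 replicate 6.

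Within each group, pairs of mice were compared by a chi-square test over genes with a summed count of at least 20. The lowest value per degree of freedom was 4.962, so no pair differed by as little as sampling noise alone gives. Groups were also split at random, up to 100 splits per comparison.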

Results

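Lung transcriptomes were measured in 19 mouse offspring whose dams received nicotine with saccharin, or saccharin alone, in the drinking water. The saccharin group held 6 mice at postnatal day 2 (4 female, 2 male) and 5 at day 16 (2 female, 3 male). The nicotine group held 5 mice at day 2 (3 female, 2 male) and 3 at day 16 (2 female, 1 male). Total counts were 12976749 to 27302477 in saccharin mice and 14431103 to 16816797 in nicotine mice at day 2. At day 16 they were 22459604 to 26355744 and 24337168 to 26673379. Sftpc, which encodes surfactant protein C of alveolar type 2 cells, was the most abundant gene in every library and held 1.79% to 4.16% of counts. The series asks how nicotine before birth and during lactation affects the lung while alveoli form, and whether changes last.

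Age separated the libraries on the first principal component of log2 CPM, which held 42.8% of the variance. On the second component, with 22% of the variance, nicotine day 2 mice lay at 38.4 to 50.2 and saccharin day 2 mice at -62.1 to 4.5. Mice of the saccharin day 2 group differed most among themselves, with a median SD of log2 CPM of 0.326. That SD was 0.136 in nicotine mice at day 2, and 0.234 and 0.123 in saccharin and nicotine mice at day 16.

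**Figure D1:**
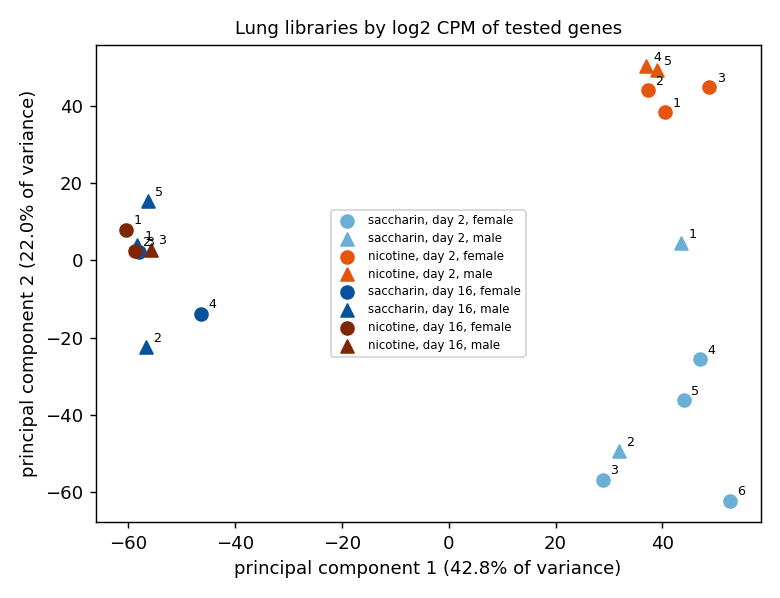
Principal components of log2 CPM for all 19 libraries, with the first component (42.8% of variance) on the x axis and the second (22%) on the y axis; each point is a mouse, coloured by group, with circles for females and triangles for males by label and the replicate number beside it. Day 16 mice sit at -60.4 to -46.4 on the x axis and day 2 mice at 28.9 to 52.7.

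At postnatal day 2, lungs of nicotine mice held more transcripts of dividing cells than lungs of saccharin mice. Mki67, a marker of proliferating cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), averaged 181 ± 24.7 CPM (SD, n = 5) against 40.1 ± 21.4 (n = 6), a 4.66-fold difference. Its log2 fold change was 2.22 (SE 0.24, adjusted p = 1.62e-05). All 25 measured genes of the mitosis list rose, and all 25 passed when adjusted over the list alone. They included Top2a, which untangles DNA (190 against 36.2 CPM), and Foxm1, a transcription factor of the G2 phase (41.3 against 11.2 CPM). The median log2 fold change of the list was 2.01, with a camera adjusted p = 3.41e-16 and an adjusted p = 0.409 with an estimated correlation. Of 24 DNA replication genes 22 rose, 0 fell and 2 did not pass, with 23 passing when adjusted over the list alone. Mcm4, a subunit of the replicative helicase (ENSMUSG00000022673, chromosome 16, 15623897 to 15637400), averaged 95.7 ± 17.2 against 35.9 ± 9.66 CPM. Its log2 fold change was 1.41 (SE 0.14, adjusted p = 7.34e-06), and Rrm1 and Rrm2, the subunits of ribonucleotide reductase, rose by 1.31 and 2.09. The median of this list was 1.29 (camera adjusted p = 1.48e-12, adjusted p = 0.409 with an estimated correlation).

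Genes of the connective tissue were also higher in nicotine mice at day 2. Col1a1, a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), averaged 1450 ± 594 CPM (SD, n = 5) against 326 ± 74.2 (n = 6). Its log2 fold change was 2.16 (SE 0.29, adjusted p = 4.95e-05). Nicotine replicate 3 stood apart, with 2500 CPM of Col1a1 against 1050 to 1340 in the other nicotine mice and a collagen score of 7.5 against 7.07 to 7.18. Without it Col1a1 differed by 1.86 (adjusted p = 0.00016) and the collagen list still passed camera. Of 24 fibrillar collagen and collagen-processing genes 18 rose, 0 fell and 6 did not pass, with 18 when adjusted over the list alone. Col3a1, the chain of type III collagen, averaged 2590 against 984 CPM. The list had a median of 0.90 (camera adjusted p = 7.74e-07, adjusted p = 0.356 with an estimated correlation). Of 19 elastic fibre genes 13 rose, 0 fell and 6 did not pass, with 15 when adjusted over the list alone. Loxl2, which cross-links matrix proteins, averaged 217 against 78.7 CPM, and Fbln5, a fibulin of elastic fibres, 628 against 312. The median was 0.68 (camera adjusted p = 1.32e-06, adjusted p = 0.356 with an estimated correlation). Elastin itself did not pass, with Eln at 1260 ± 274 against 1020 ± 554 CPM (log2 fold change 0.34, SE 0.33, adjusted p = 0.417). Of 22 basement membrane genes 15 rose, 0 fell and 7 did not pass, with 16 when adjusted over the list alone, and Col15a1 averaged 61.3 ± 4.17 against 11.9 ± 4.14 CPM. Their median was 0.76 (camera adjusted p = 9.66e-06, adjusted p = 0.513 with an estimated correlation).

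Contractile and vessel-wall genes followed the same direction at day 2. Myh11, the myosin heavy chain of smooth muscle (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372), averaged 211 ± 47.9 CPM (SD, n = 5) against 60 ± 19 (n = 6), with a log2 fold change of 1.8 (SE 0.2, adjusted p = 1.81e-05). Of 17 myofibroblast and smooth muscle genes 11 rose, 0 fell and 6 did not pass, with 13 when adjusted over the list alone. Their median was 0.77 (camera adjusted p = 6e-05, adjusted p = 0.227 with an estimated correlation). Acta2, smooth muscle actin, rose by 0.95 (SE 0.23, adjusted p = 0.00354), and Pdgfra, the receptor that marks myofibroblast precursors, by 0.74 (SE 0.28, adjusted p = 0.0395). Pdgfra no longer passed without nicotine replicates 2, 4 or 5 (adjusted p = 0.0799, 0.0726 and 0.0711). The same held without saccharin replicates 1 to 5 (0.0589, 0.0987, 0.0701, 0.0666 and 0.05). Its log2 fold change was 0.40 after the length and GC correction (adjusted p = 0.11), 0.52 in females (0.333) and 0.53 in the second number run alone (0.335). Of 11 pericyte genes 7 rose, 0 fell and 4 did not pass, with 7 when adjusted over the list alone. Cspg4 averaged 34.4 against 13.8 CPM and Gucy1a1, a subunit of the nitric oxide receptor, 492 against 210. The camera adjusted p = 0.00156 of this list became an adjusted p = 0.356 with an estimated correlation.

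Among endothelial genes, capillary and angiogenesis lists held more higher than lower members in nicotine mice at day 2. Vegfd, a growth factor of blood and lymph vessels (ENSMUSG00000031380, chromosome X, 164373378 to 164402650), averaged 104 ± 7.88 CPM (SD, n = 5) against 35.4 ± 8.66 (n = 6). Its log2 fold change of 1.55 (SE 0.11) had the smallest adjusted p of all genes, 3.07e-07. Of 18 capillary genes 10 rose, 2 fell and 6 did not pass (11 and 2 adjusted over the list alone), with Cdh5, the cadherin of endothelial junctions, at 761 against 385 CPM. Of 23 angiogenesis genes 10 rose, 3 fell and 10 did not pass (10 and 3 adjusted over the list alone), and Esm1 fell from 16.9 to 6.01 CPM. Of 13 arterial and venous genes 4 rose and 2 fell (camera adjusted p = 0.0874, and 0.0353 without nicotine replicate 3 and saccharin replicate 6), and of 10 lymphatic genes 0 rose and 3 fell (camera adjusted p = 0.657). Camera gave an adjusted p = 0.00631 for capillary and 0.0157 for angiogenesis genes. These were an adjusted p = 0.439 and an adjusted p = 0.513 with an estimated correlation. Vegfa, the main endothelial growth factor of the alveolar epithelium, was lower, at 481 ± 44.6 against 768 ± 133 CPM (log2 fold change -0.67, SE 0.13, adjusted p = 0.00089).

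Inflammatory genes were lower in nicotine mice at day 2, and varied widely among the saccharin mice. Saa3, an acute phase protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), averaged 14.1 ± 9.34 CPM (SD, n = 5) against 462 ± 378 (n = 6), with a log2 fold change of -5.11 (SE 0.56, adjusted p = 1.81e-05). All 24 measured inflammatory cytokine and NF-kB target genes fell, and all 24 passed when adjusted over the list alone. Lcn2, an iron-binding protein of neutrophils and epithelium, averaged 145 against 1020 CPM and Ccl20, a chemokine, 1.23 against 32. The median log2 fold change was -4.13 (camera adjusted p = 4.63e-12, adjusted p = 0.409 with an estimated correlation). Orm1, an acute phase protein whose counts are uncertain because Orm2 is near-identical, averaged 0.476 ± 0.247 against 46 ± 42 CPM. Orm2 averaged 0.0736 ± 0.031 against 7.29 ± 5.45 CPM (log2 fold change -6.42, SE 0.56, adjusted p = 3.91e-06). The chemokines Cxcl2, Cxcl3, Ccl3 and Ccl4, the granulocyte factor Csf3 and Acod1, which makes itaconate in macrophages, were the others of the 8 largest decreases. Each was below 2 CPM on average in nicotine mice, and Acod1 averaged 0.869 against 132 ± 268. Saccharin replicate 6 carried these saccharin means, with 679 CPM of Acod1, 1580 of Cxcl2 and 826 of Ccl3 against 10.2 to 37.6, 3.37 to 50 and 4.07 to 33.7 in the other 5. It also held 93.4 CPM of Cxcl3, 159 of Ccl4 and 69.8 of Csf3. Without it the log2 fold changes of Cxcl2, Cxcl3, Ccl3, Ccl4, Csf3 and Acod1 were -3.86, -4.54, -3.31, -3.66, -4.9 and -4.72, and all 6 still passed. With blocks of consecutive mouse numbers as a random effect none of these 6 passed, at an adjusted p of 0.175, 0.0608, 0.151, 0.0855, 0.149 and 0.0691 in that order. Cxcl2 and Ccl3 did not pass with counts summed per block either (adjusted p = 0.0847 and 0.0607). Both kept their direction there, and with 2 blocks per agent a lost call does not show a smaller difference. Of 15 neutrophil genes 1 rose, 9 fell and 5 did not pass (1 and 9 adjusted over the list alone), with Csf3r, the receptor of granulocyte growth factor, at 21.6 against 88.3 CPM. Their camera adjusted p = 0.00156 became an adjusted p = 0.513 with an estimated correlation. The mean log2 CPM of the inflammatory list ran from 3.8 to 8.34 in saccharin mice and from 2.14 to 3.07 in nicotine mice. The highest value belonged to saccharin replicate 6.

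Glutathione and oxidative stress genes were lower as well, with 18 of 24 falling, 0 rising and 6 not passing, and 18 falling when adjusted over the list alone. Gpx2, a glutathione peroxidase, averaged 7.95 against 36 CPM, and Srxn1, which restores peroxiredoxins, 20.4 against 55.4. The camera adjusted p = 1.32e-06 became an adjusted p = 0.409 with an estimated correlation. Of 19 endoplasmic reticulum stress genes 2 rose and 10 fell, and 1 rose and 8 fell of 22 hypoxia and glycolysis genes. Of 17 glucocorticoid response genes 1 rose and 7 fell. Camera gave an adjusted p of 0.018, 0.0164 and 0.0273 for these lists, and an adjusted p = 0.516, 0.513 and 0.685 with an estimated correlation. Without saccharin replicate 6 the glucocorticoid list had an adjusted p of 0.149. After a correction for gene length and GC content these 3 lists did not pass, at an adjusted p of 0.644, 0.598 and 0.206. Their medians went from -0.446 to -0.242, from -0.389 to -0.378 and from -0.752 to -0.715. The hypoxia and glucocorticoid medians thus hardly moved, and their lost calls do not show that the length trend accounts for them. Camera's direction for endoplasmic reticulum stress, set against all other genes, then turned to higher, with 4 members higher and 6 lower.

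Epithelial markers were lower in nicotine mice at day 2. Sftpd, surfactant protein D of innate defence (ENSMUSG00000021795, chromosome 14, 41172214 to 41185149), averaged 842 ± 118 CPM (SD, n = 5) against 2570 ± 516 (n = 6), with a log2 fold change of -1.61 (SE 0.16, adjusted p = 7.42e-06). Of 16 alveolar type 2 genes 1 rose, 10 fell and 5 did not pass (1 and 10 adjusted over the list alone). Their median was -0.40 (camera adjusted p = 0.000427, adjusted p = 0.356 with an estimated correlation). Sftpc averaged 18200 ± 1390 against 27600 ± 7370 CPM (log2 fold change -0.61, SE 0.17, adjusted p = 0.00978), and did not pass after a length and GC correction (adjusted p = 0.657). Of 22 surfactant genes 1 rose and 10 fell (camera adjusted p = 0.00761, adjusted p = 0.439 with an estimated correlation). Ager, a marker of the flat alveolar type 1 cells, averaged 1920 ± 130 against 3740 ± 778 CPM (log2 fold change -0.95, SE 0.14, adjusted p = 0.000113), while the type 1 list as a whole did not pass (camera adjusted p = 0.222). Of 14 club cell genes 7 fell and 0 rose, and of 15 ciliated cell genes 10 fell and 0 rose (camera adjusted p = 0.000753 and 0.00194). With an estimated correlation they had an adjusted p = 0.448 and an adjusted p = 0.439. The club score of nicotine replicates 1 to 3 was 6.85 to 7.55, within the 6.7 to 8.29 of saccharin mice, while replicates 4 and 5, 1 block of mouse numbers, had 5.02 and 6.08. The ciliated score was 4.13 to 4.72 in nicotine and 4.61 to 5.09 in saccharin mice. Inmt, a methyltransferase of lung fibroblasts, averaged 10.7 ± 3.83 against 198 ± 145 CPM (log2 fold change -4.07, SE 0.4, adjusted p = 7.34e-06).

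Blood-cell and growth lists also passed camera at day 2. Of 15 erythroid genes 12 rose, 0 fell and 3 did not pass, with 13 when adjusted over the list alone, and Slc4a1, the anion exchanger of red cells, averaged 66.5 ± 47.1 against 9.8 ± 3.2 CPM. Nicotine replicate 3 had the highest erythroid score. The camera adjusted p = 9.39e-05 became an adjusted p = 0.439 with an estimated correlation. B cell genes (5 higher, 1 lower of 14), MHC class II and dendritic genes (5 and 1 of 15) and thymus genes (4 and 0 of 7) had a camera adjusted p of 0.0164, 0.0143 and 0.0164. The MHC class II score of saccharin replicates 1 to 3, 1 block of mouse numbers, was 2.37 to 2.98 and overlapped the 2.56 to 3.01 of nicotine mice. Saccharin replicates 4 to 6, the other block, had 1.04 to 1.54. The B cell score was 2.17 to 2.61 and 1.25 to 1.67 in these blocks and 2.49 to 2.72 in nicotine mice. Of 25 hedgehog, FGF and PDGF genes 14 rose and 0 fell, with Hhip, a hedgehog inhibitor, at 77.3 against 34.1 CPM (camera adjusted p = 0.000556, adjusted p = 0.409 with an estimated correlation). Wnt genes rose in 11 and fell in 4 of 25 cases (camera adjusted p = 0.0273), and insulin-like growth factor and imprinted genes in 10 and 2 of 21 (0.0136). None of these lists passed with an estimated correlation, for which the smallest adjusted p of any list was 0.227.

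Ribosomal protein genes were lower, with 24 of 39 falling, 1 rising and 14 not passing, and 32 falling when adjusted over the list alone. Their median was -0.57 (camera adjusted p = 2.79e-06, adjusted p = 0.513 with an estimated correlation), and Rps19 averaged 213 against 422 CPM. Of 33 nuclear oxidative phosphorylation genes 7 fell and 0 rose (camera adjusted p = 0.0182, adjusted p = 0.698 with an estimated correlation). Without saccharin replicates 2 or 3 that list did not pass (0.0716 and 0.0953). Counts of ribosomal proteins are uncertain because many processed pseudogenes resemble them. Log2 fold changes at day 2 followed gene length, with a Spearman rho of 0.463 across 15113 genes, which are not independent replicates. The median was -0.41 in the shortest quintile of genes and 0.37 in the longest. After a correction for length and GC content the ribosomal median was -0.15, with 8 genes lower, and the list no longer passed camera (adjusted p = 0.0858), whose direction against other genes turned to higher. The oxidative phosphorylation median went from -0.31 to 0.04, with 4 genes higher and 1 lower, and camera then called the list higher than other genes (adjusted p = 0.00141). The basement membrane, angiogenesis, ciliated, club and neutrophil lists no longer passed after it, at an adjusted p of 0.281, 0.281, 0.264, 0.129 and 0.0661. Their medians went from 0.763 to 0.412, 0.492 to 0.205, -0.686 to -0.384, -0.763 to -0.537 and -2.519 to -2.184. The neutrophil list still had 9 members lower and 1 higher, so its lost call does not show that the trend accounts for it. The thymus and the insulin-like growth factor and imprinted lists also lost their calls (0.0858 and 0.281). Their medians went from 0.657 to 0.83 and from 0.563 to 0.462, so these losses do not show that the trend accounts for them.

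**Figure D2:**
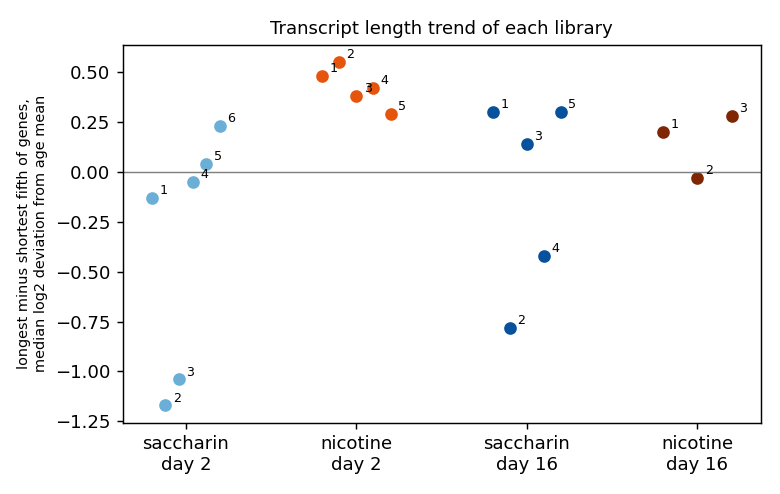
Difference between the longest and shortest quintile of genes in each library, as the median log2 deviation from the mean of the same age (y axis), for each of the 19 mice by group and replicate. Saccharin day 2 replicates 2 and 3 sit at -1.17 and -1.04 and saccharin day 16 replicates 2 and 4 at -0.78 and -0.42, while nicotine day 2 mice sit at 0.29 to 0.55.

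The 8 largest rises at day 2 were mostly skeletal muscle genes, with high levels in 1 library. Myh8, a myosin of developing muscle, read 892 CPM in nicotine replicate 3 and 1.18 to 2.06 in the other 4 nicotine mice. Car3, Atp2a1, Mylpf, Ryr1 and Neb shared this pattern, and Xirp2 and Col10a1, a collagen of cartilage, were among the same 8. Without replicate 3, Car3, Myh8, Atp2a1, Mylpf, Ryr1 and Neb had log2 fold changes of -0.68, -1, -1.94, -2.08, -0.48 and -0.07, of which Mylpf alone passed (adjusted p = 0.0481), and Xirp2 was 0.11 (adjusted p = 0.934). Saccharin replicate 6 read 23.8, 18.6 and 55.5 CPM of Myh8, Atp2a1 and Mylpf. The other saccharin mice had 0.645 to 1.63, 0.645 to 1.16 and 3.08 to 5.53. Without nicotine replicate 3 and saccharin replicate 6 together, these 3 genes had log2 fold changes of 0.84, -0.16 and -0.68 (adjusted p = 0.15, 0.653 and 0.0188). Col10a1 still passed without replicate 3, with a log2 fold change of 1.14 (adjusted p = 0.0151). It read 60.8 CPM in that library and 0.718 to 2.19 in the other nicotine mice, and did not pass without that library and saccharin replicates 2 and 3 (0.94, adjusted p = 0.0772). The mean log2 CPM of the skeletal muscle list was 8.71 in that library and 0.524 to 1.1 in the other nicotine mice. As a list it did not pass (camera adjusted p = 0.551).

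Nicotinic receptor genes were near the detection limit. Chrna7 averaged 0.122 CPM in nicotine and 0.153 in saccharin mice at day 2, and Chrnb4 0.326 and 0.508 (adjusted p = 0.668 and 0.355). Chrna3 and Chrna5 had too few counts for a test, with at most 11 and 2 reads in any library. The list of nicotinic receptor and cholinergic genes did not pass (2 higher and 1 lower of 14, camera adjusted p = 0.927).

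In all, 6223 of 15143 genes passed edgeR at day 2, with 2940 higher and 3283 lower in nicotine mice, and 1650 differed at least 2-fold. Camera called 28 of 56 lists, 16 higher and 12 lower. The count was 1064 in the first run of mouse numbers alone, 4412 in the second, 6714 with a term for the run and 3818 in females. It was 3230 with blocks of consecutive mouse numbers as a random effect in limma-voom. With counts summed per block and no sex term it was 1528. These block counts therefore do not isolate the effect of the blocks. Of the other genes tested this way, Pdgfra and Sftpc did not pass with random-effect blocks (adjusted p = 0.0625 and 0.0565). With block sums Pdgfra, Acta2, Sftpc and Vegfa did not pass (adjusted p = 0.162, 0.0647, 0.18 and 0.0753), and none of the 8 largest rises passed either way. Pdgfra, Acta2, Sftpc and Vegfa kept their direction with block sums, which leave few units, so these lost calls do not show smaller differences. Each agent had 2 such blocks at day 2, and the labels do not say whether these were litters. In the second run of mouse numbers every nicotine mouse was male and every saccharin mouse female, so its count cannot separate agent from sex. Nicotine females were all of the first run and most saccharin females of the second, so the count in females largely mixes run and agent.

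**Figure D3:**
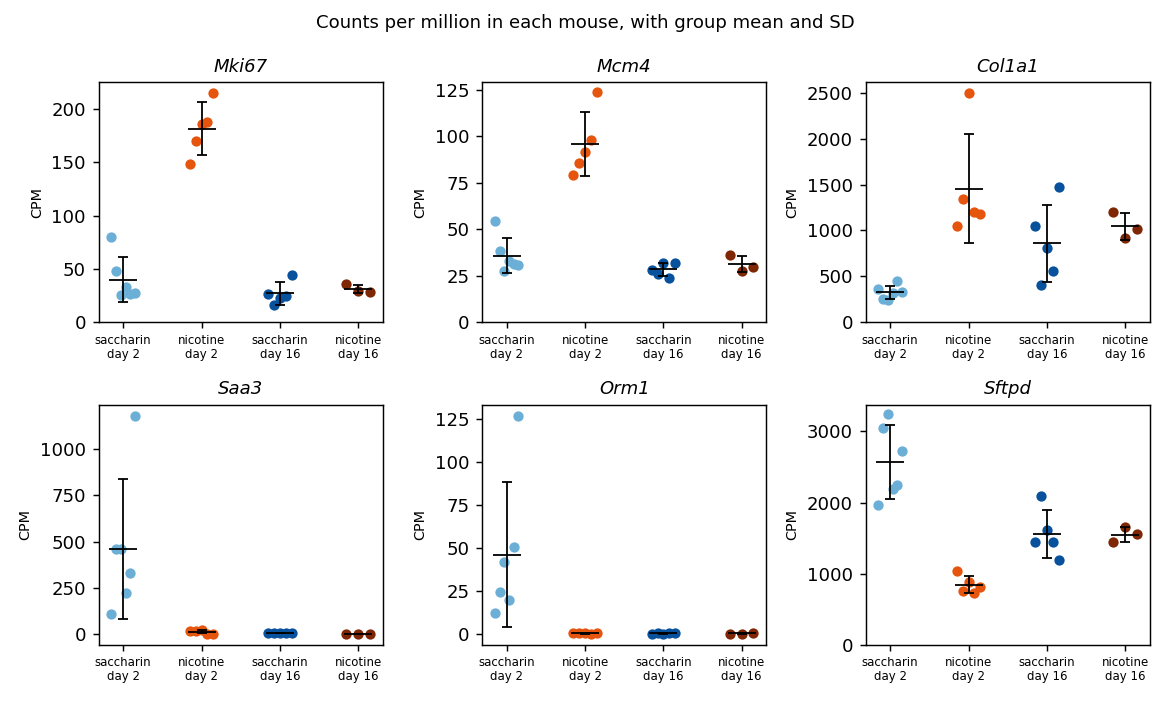
CPM per mouse (points) with the mean and SD for Mki67, Mcm4, Col1a1, Saa3, Orm1 and Sftpd in the 4 age and agent groups. At day 2 Mki67 averaged 181 CPM in nicotine and 40.1 in saccharin mice, and 31.1 and 27.1 at day 16.

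**Figure D4:**
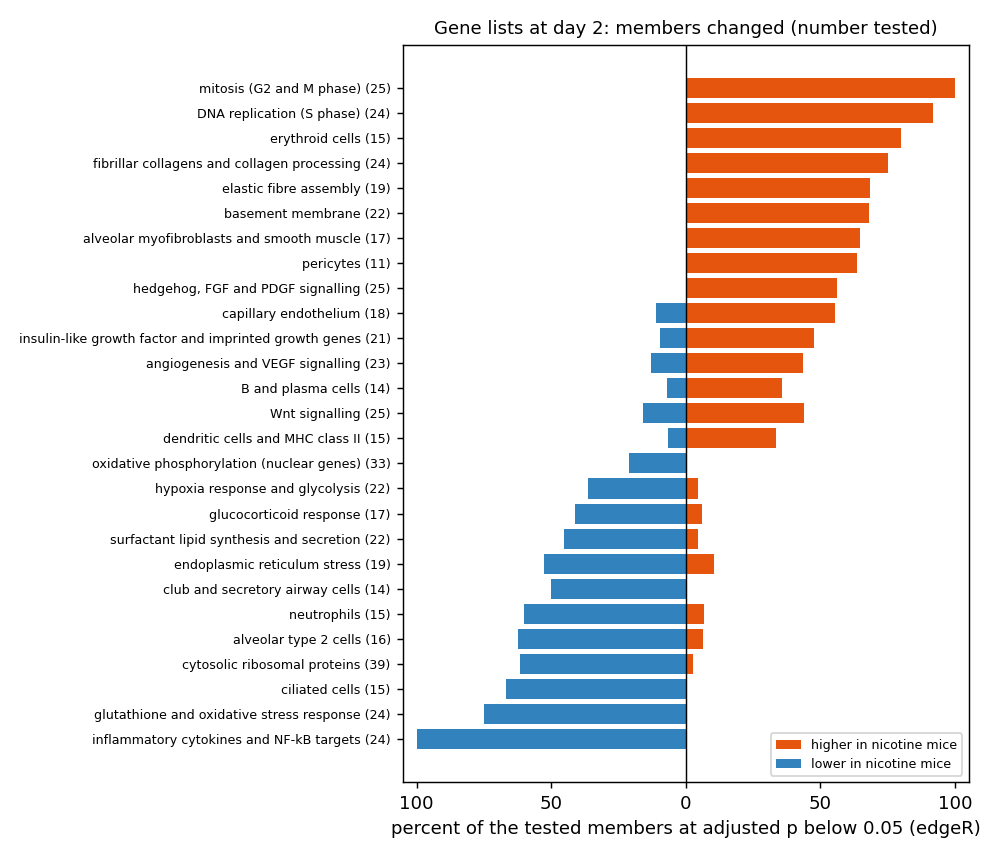
Percent of tested members that were higher (orange) or lower (blue) in nicotine mice at day 2 for the 27 cell-type and pathway lists with a camera adjusted p under 0.05 (x axis in percent, 1 pair of bars per list). All 25 mitosis genes were higher and all 24 inflammatory genes lower; no list passed with an estimated correlation.

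At day 16, 0 genes passed edgeR between nicotine and saccharin mice. At an unadjusted p under 0.05 there were 311 genes, against 757.2 from chance alone, while DESeq2 called 12 and limma-voom 2. A number below chance does not show that no gene differed, and its cause was not tested. All groups shared 1 estimate of spread per gene. The median SD of log2 CPM was 0.326 in saccharin day 2 mice, and 0.234 and 0.123 in saccharin and nicotine mice at day 16. Chil4, a chitinase-like protein of type 2 inflammation whose counts are uncertain beside near-identical Chil3 (ENSMUSG00000063779, chromosome 3, 106201490 to 106219507), averaged 7.95 ± 5.44 CPM (SD, n = 3) in nicotine mice and 63.3 ± 31.3 (n = 5) in saccharin mice. Its log2 fold change was -3.36 (SE 0.54, adjusted p = 0.0517). Retnla, a secreted product of the same response, averaged 173 ± 55.3 against 557 ± 253 CPM (log2 fold change -1.76, SE 0.34, adjusted p = 0.168). Cacng7, a calcium channel subunit (ENSMUSG00000069806, chromosome 7, 3332955 to 3368221), averaged 40.3 ± 39.9 against 6.11 ± 1.51 CPM (adjusted p = 0.0517). Cend1 and Clip3, genes best known from neurons, averaged 33.7 ± 53.8 against 0.322 ± 0.097 and 35.4 ± 28.7 against 9.19 ± 2.46 CPM (adjusted p = 0.0684 and 0.0924). Nicotine replicate 1 set the size of these last 3 differences, at 86.4, 95.9 and 68.6 CPM for Cacng7, Cend1 and Clip3. Replicates 2 and 3 had 18.4 and 16.1, 3.23 and 2.05, and 19.2 and 18.5 CPM, above every saccharin mouse (at most 8.66, 0.465 and 13.3). Without replicate 1 the log2 fold changes were 1.5, 2.96 and 1.06 (adjusted p = 0.0687, 0.106 and 0.267). Leaving out nicotine replicate 2 or 3 gave 5 or 7 passing genes, and Cacng7, Cend1 and Clip3 passed in each case (adjusted p 0.00464 to 0.0215). Chil4 passed without nicotine replicate 2 or saccharin replicates 1 or 2 (adjusted p = 0.0324, 0.0233 and 0.0296). Chil4 and Cacng7 also passed without saccharin day 2 replicate 6 (adjusted p = 0.036 for each), which entered the shared estimate of spread.

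The alveolar genes given in every comparison had similar means at day 16, each with an adjusted p of 1. Eln averaged 4080 ± 121 CPM (SD, n = 3) in nicotine and 4000 ± 1850 (n = 5) in saccharin mice, and Col1a1 1040 ± 144 and 858 ± 419. Eln read 5070, 4390 and 6290 CPM in saccharin replicates 1, 3 and 5, above every nicotine mouse (3940 to 4170). It read 2400 and 1860 in saccharin replicates 2 and 4, the day 16 libraries of the strongest length trend, so the similar means rest on those libraries. Pdgfra averaged 337 and 344 CPM, Acta2 189 and 214, Sftpc 30500 and 32500, Ager 4160 and 4100, Vegfa 957 and 867, and Mki67 31.1 and 27.1. Chrna7 averaged 0.737 and 0.498 CPM, and Chrnb4 0.24 and 0.0678. At this group size 55% of simulated 2-fold and 95% of simulated 4-fold changes were recovered, with independent mice and 1 spread per gene in all groups. In the real data Chil4 and Cend1, with 10.3-fold and 65.7-fold differences, did not pass. The simulated shares therefore do not say that a real 4-fold change would have been found.

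Camera called 19 lists at day 16, 10 higher and 9 lower in nicotine mice, although 0 members of any list passed over all genes. Megakaryocyte and platelet genes led with a median log2 fold change of 0.58 over 10 genes (camera adjusted p = 1.37e-10, adjusted p = 0.0976 with an estimated correlation). Of these, 2 passed when adjusted over the list alone, and Itga2b, the platelet integrin, averaged 25.9 against 16.2 CPM. Collagen genes had a median of 0.21 (camera adjusted p = 2.47e-05, adjusted p = 0.766 with an estimated correlation). T and natural killer cell genes had a median of -0.33 (camera adjusted p = 0.000718, adjusted p = 0.766 with an estimated correlation). Log2 fold changes followed gene length at this age too, with a Spearman rho of 0.371. Without nicotine replicate 1, 8 lists passed. After the length and GC correction 8 lists passed as well, and collagen and T cell genes did not (adjusted p = 0.491 and 0.14). The T cell list was also lost without nicotine replicate 3 (adjusted p = 0.214). Nicotine replicate 2, labelled female, carried Y-linked transcripts at male level, and 2 genes passed when it was taken as male.

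Whether the nicotine effect differed between the ages was tested directly, and 874 genes passed, 493 with the higher and 381 with the lower value at day 16. Mitosis genes had a lower nicotine effect at day 16 in 19 of 25 cases, and in 25 when adjusted over the list alone (median difference -2.01, camera adjusted p = 5.63e-19). With an estimated correlation this list had an adjusted p = 0.426. For Mki67 the difference was -1.85 (adjusted p = 0.0165). Inflammatory genes had a higher effect at day 16 in 8 of 24 cases and in 17 when adjusted over the list alone (median 3.59, camera adjusted p = 3.67e-12, adjusted p = 0.468 with an estimated correlation). Saa3 differed by 4.18 and Orm1 by 6.2 (adjusted p = 0.0132 for each, and 0.0963 for Orm1 without nicotine day 16 replicate 3), and Sftpd by 1.59 (adjusted p = 0.00768). Collagen genes had a lower effect at day 16 in 6 of 24 cases (camera adjusted p = 0.000161, adjusted p = 0.47 with an estimated correlation), with Col1a1 at -1.89 (adjusted p = 0.0272). Type 2 cell genes had a higher effect in 4 of 16 cases (camera adjusted p = 0.000161, adjusted p = 0.337 with an estimated correlation).

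The count of 874 moved with single mice. It was 3 without nicotine day 16 replicate 3, 343 without replicate 2 and 453 without replicate 1. It was 458, 249, 434 and 575 without nicotine day 2 replicates 1, 2, 3 and 5. Without saccharin day 16 replicates 2, 3 and 5 it was 1312, 245 and 525, and without saccharin day 2 replicates 1 and 2 it was 2109 and 553. With the mouse-number blocks as a random effect in limma-voom it was 2. The 3 nicotine day 16 mice formed 1 block, so this lower count does not show that the effects at the ages were alike. Counts summed per block leave that group a single unit and cannot decide this difference.

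Development in the saccharin mice was the second age comparison, and 6486 genes differed between day 16 and day 2, with 3108 higher and 3378 lower at day 16. Adaptive immune genes were higher. All 15 MHC class II and dendritic cell genes rose, and H2-Eb1, which presents antigen, averaged 283 ± 40.1 CPM (SD, n = 5) at day 16 against 23.3 ± 19.4 (n = 6) at day 2. Their median was 2.59 (camera adjusted p = 6.96e-10, adjusted p = 0.291 with an estimated correlation). Of 14 B cell genes 13 rose (camera adjusted p = 6.14e-08, adjusted p = 0.259 with an estimated correlation), and of 16 T and natural killer cell genes 13 rose and 1 fell (camera adjusted p = 9.86e-07, adjusted p = 0.353 with an estimated correlation). Of 18 capillary genes 16 rose and 0 fell, with Plvap, of endothelial fenestrae (ENSMUSG00000034845, chromosome 8, 71497765 to 71511752), at 585 ± 112 against 149 ± 26.4 CPM. The capillary median was 1.05 (camera adjusted p = 1.27e-07, adjusted p = 0.259 with an estimated correlation). Eng, an endothelial receptor of TGF-beta ligands, averaged 738 ± 180 against 185 ± 19.7 CPM, and 17 of 23 angiogenesis genes rose and 2 fell.

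Matrix genes were also higher at day 16 in the saccharin mice. Eln averaged 4000 ± 1850 against 1020 ± 554 CPM (log2 fold change 2.1, SE 0.36, adjusted p = 0.000155), and 12 of 19 elastic fibre genes rose and 1 fell (camera adjusted p = 0.000759, adjusted p = 0.353 with an estimated correlation). Of 24 collagen genes 15 rose and 0 fell, and Col1a1 rose by 1.41 (adjusted p = 0.00105). After the length and GC correction neither list passed (camera adjusted p = 0.364 and 0.235). The collagen score was 6.196 to 6.472 in saccharin day 2 mice. In nicotine mice it was 7.068 to 7.502 at day 2 and 7.042 to 7.243 at day 16. Elastic fibre scores were 6.745 to 7.091, 7.571 to 7.839 and 7.674 to 7.895 in the same order. The size of these list rises thus rests on the low values of the saccharin day 2 mice. Eln itself averaged 1260 and 4080 CPM in nicotine mice of day 2 and day 16. Pdgfra averaged 344 against 78.6 CPM and Acta2 214 against 462, both past the threshold, although Acta2 missed it with counts summed per block (adjusted p = 0.0501). Sod3, extracellular superoxide dismutase (ENSMUSG00000072941, chromosome 5, 52363791 to 52371418), averaged 415 ± 74.7 against 36.7 ± 13.3 CPM (log2 fold change 3.57, SE 0.21, adjusted p = 2.3e-09). Clca1, a secreted goblet cell protein, averaged 258 ± 130 CPM at day 16 and 0.13 at day 2, and Chil4 63.3 and 0.125. The other 6 of the 8 largest rises were Cfd, Adra1a, Crabp1, Slc5a12, Tff2 and C7, with log2 fold changes of 6.2, 5.58, 5.39, 5.35, 4.9 and 4.59. Of these Tff2 missed the threshold with block sums (adjusted p = 0.0986). Cd209a, a lectin of dendritic cells, rose by 4.49, and Vegfd by 1.43. Vegfd read 29 to 52.3 CPM in saccharin day 2 mice and 88 to 107 in saccharin day 16 mice. In nicotine mice it read 96 to 112 at day 2 and 107 to 110 at day 16. Its rise thus rests on the low values of the saccharin day 2 mice.

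Fetal growth, inflammatory and translation genes were lower at day 16. Dlk1, an imprinted growth regulator (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336), averaged 1.9 ± 0.589 against 89.3 ± 31 CPM, and Igf2bp3, a fetal RNA-binding protein, 4.72 against 37.5. Of 21 insulin-like growth factor and imprinted genes 3 rose and 13 fell (camera adjusted p = 0.00708, adjusted p = 0.353 with an estimated correlation). Of 24 inflammatory genes 0 rose and 22 fell, with a median of -5.01 (camera adjusted p = 2.63e-09, adjusted p = 0.353 with an estimated correlation), and of 15 neutrophil genes 14 fell. The mean inflammatory score was 5.54 at day 2 and 2.05 at day 16 in saccharin mice, but 2.49 and 1.85 in nicotine mice. The size of this fall thus rests on the high values of the saccharin day 2 mice. The 8 largest decreases were Acod1, Cxcl2, Ccl20, Csf3, Ccl3, Acta1, Orm1 and Il6, with log2 fold changes of -9.68, -9.19, -7.92, -7.81, -7.5, -6.9, -6.83 and -6.81. Acod1, Cxcl2, Csf3, Ccl3 and Orm1 were also among the largest decreases of nicotine mice at day 2, against the same saccharin mice. With random-effect blocks Acod1, Cxcl2, Csf3, Ccl3 and Acta1 did not pass (adjusted p = 0.0573, 0.137, 0.135, 0.0984 and 0.4), nor Cxcl2 and Acta1 with block sums (0.0533 and 0.231). Acta1 was barely past the threshold (adjusted p = 0.0487) and missed it without saccharin day 2 replicate 6 (-4.84, adjusted p = 0.136). It also missed it without any of 10 other mice (0.0576 to 0.136). Without replicate 6 Acod1, Cxcl2, Csf3, Ccl3 and Il6 still passed, with log2 fold changes of -7.78, -6.45, -5.41, -5.1 and -5.68. Tgfbi, a matrix protein, fell by 2.42 and Egln3, an oxygen sensor, by 3.05. Of 39 ribosomal protein genes 22 fell (camera adjusted p = 3.51e-06, adjusted p = 0.546 with an estimated correlation). Of 24 DNA replication genes 16 fell (camera adjusted p = 0.00183, adjusted p = 0.715 with an estimated correlation). The DNA replication score was 3.98 to 4.677 in saccharin day 2 replicates 1 to 3, 1 block of mouse numbers. In replicates 4 to 6, the other block, it was 3.05 to 3.735 and overlapped the 3.254 to 3.612 of saccharin day 16 mice. The mitosis list did not pass (6 of 25 lower, camera adjusted p = 0.0842). It passed without saccharin day 16 replicate 4 or saccharin day 2 replicates 5 or 6 (0.0228, 0.0395 and 0.00769). Mki67 fell by 0.63 on the log2 scale (adjusted p = 0.0428), and by 0.35 without saccharin day 2 replicate 1 (adjusted p = 0.198). It also missed the threshold without any of 9 other mice, at an adjusted p of 0.0508 to 0.0899, with random-effect blocks (0.159) and with block sums (0.436). Sftpc, Ager and Vegfa did not pass, with log2 fold changes of 0.2, 0.16 and 0.19. Chrnb4 fell from 0.508 to 0.0678 CPM (log2 fold change -2.5, adjusted p = 0.000777) and Chrna7 rose from 0.153 to 0.498 (1.5, adjusted p = 0.0299). Chrna7 missed the threshold without saccharin day 16 replicate 3 or saccharin day 2 replicates 1 or 5 (0.112, 0.0763 and 0.0514). It also missed it with random-effect blocks (0.139) and block sums (0.0873). All saccharin day 16 mice came from 1 run of mouse numbers that held no day 2 mouse, so age and number run cannot be told apart.

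Between the sexes, 4 genes passed, and all were Y-linked. Ddx3y, an RNA helicase (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), averaged 4.38 ± 14 CPM (SD, n = 11) in mice labelled female and 74.1 ± 35.4 (n = 8) in mice labelled male. Eif2s3y, Kdm5d and Uty averaged 3.19 against 60.6, 2.21 against 29.6 and 0.821 against 19.3 CPM. Nicotine day 16 replicate 2, labelled female, held 112 CPM of these 4 genes together, while the 8 males held 106 to 324 and the other 10 females 0 to 2.38. Camera called 24 lists between the sexes, led by mitosis genes with a median of -0.62 (adjusted p = 3.18e-18), which had an adjusted p = 0.487 with an estimated correlation, and all 25 of them passed as lower in females when adjusted over the list alone. In nicotine mice of day 2 the females were 1 block of mouse numbers and the males the other, so sex and block cannot be told apart there. Saccharin day 2 replicates 4 to 6, a block of females only, had mitosis scores of 2.06 to 2.93. The males of the other block, replicates 1 and 2, had 4.61 and 4.06, and its female 3.1. No member of any tested list passed over all genes in this comparison, where edgeR found 916 genes at an unadjusted p under 0.05, DESeq2 called 10 genes and limma-voom 32.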

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

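The tests of the Y-linked transcripts were chosen after their result was seen, as were the length and GC correction, the removal of 3 unusual saccharin libraries, the random-effect blocks and the block sums as alternatives, and the splits that keep blocks whole.

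Single mice stood far from their group in 41 of 366 checks of totals, list scores and named genes, against 18.3 that chance gives at about 1 in 20 groups. The nicotine day 16 group, with only 3 mice, was too small for these checks and was left out. Many of the named genes were picked for large differences in these data, and the checks share signals, so these counts are not a test of excess. Each value below is the gap to the nearest mouse divided by the whole range of the group, both taken on the log2 CPM scale. Nicotine day 2 replicate 3 gave 16 of the 41. It was highest in the scores of skeletal muscle (0.93), fat (0.808), erythroid (0.775), collagen (0.749) and metalloproteinase genes (0.785). It was also highest in Acta1 (0.942), Atp2a1 (0.928), Myh8 (0.92), Neb (0.916), Mylpf (0.904), Ryr1 (0.827), Car3 (0.777), Col10a1 (0.762) and Col1a1 (0.718). For Orm2 (0.853) and Cfd (1) its level was only 0.129 CPM. Saccharin day 2 replicate 6 gave 13. It was highest in the scores of neutrophil (0.638), skeletal muscle (0.831), glucocorticoid (0.733), p53 (0.673) and TGF-beta genes (0.679). The same held for Myh8 (0.758), Atp2a1 (0.837), Mylpf (0.801), Acta1 (0.835), Acod1 (0.691), Ccl4 (0.633) and Il1r2 (0.639), and it was lowest in Crabp1 (0.701).

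Of the other mice checked, those that were flagged gave 1 or 2 each. Saccharin day 2 replicate 1 was highest in Vegfd (0.68) and Knl1 (0.834). Nicotine day 2 replicate 1 was highest in Cxcl2 (0.741) and Ccl3 (0.785), replicate 4 was highest in Vegfa (0.858) and lowest in Retnla (0.787), and replicate 5 was highest in Egln3 (0.741). At day 16, saccharin replicate 5 was lowest in the club cell score (0.711) and replicate 1 in Ryr1 (0.823). Replicate 4 was lowest in Sod3 (0.75). Replicate 2 was lowest in the nicotinic receptor score (0.736) and highest in Sftpc (0.71), with 45600 CPM against 27100 to 31500 in the others.

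The nicotine effect differed between the ages, by the test of the difference itself, for 874 genes. Large differences on the log2 scale, day 16 less day 2, were in Orm1 (6.2), Il1r2 (5.71), Tarm1 (5.68), Cend1 (5.6) and Orm2 (5.57). On the other side were Chil4 (-3.87), Knl1 (-2.86) and Slc4a1 (-2.84). Some sizes rested on single mice. Without saccharin day 2 replicate 6 the values were 3.63 for Il1r2 and 4.42 for Tarm1, and without replicate 1 -3.75 for Knl1. Cend1 was 2.54 without nicotine day 16 replicate 1. Without nicotine day 16 replicate 3 Orm1, Il1r2, Tarm1 and Cend1 were 5.19, 3.78, 3.98 and 6.69. Each of these 8 genes lost their call without nicotine day 16 replicate 3 (adjusted p 0.0649 to 0.289), which left 3 genes in all. The other single mice that moved the count by over 1.5 times are named with their counts above. Knl1 also lost its call without saccharin day 16 replicate 3, nicotine day 16 replicate 2 or nicotine day 2 replicate 2 (0.0569, 0.0632 and 0.0501). Orm2 lost it without saccharin day 16 replicate 3, nicotine day 16 replicates 1 and 2 or nicotine day 2 replicates 1 to 3 (0.0522 to 0.119). Tarm1 lost it without saccharin day 16 replicates 3 and 5, nicotine day 16 replicate 2, nicotine day 2 replicates 1, 2, 3 and 5 or saccharin day 2 replicate 2 (0.05 to 0.0753). Cend1 lost it without saccharin day 16 replicates 3 to 5, nicotine day 16 replicate 1, nicotine day 2 replicates 1 to 3 or saccharin day 2 replicates 2 and 3 (0.0528 to 0.0941). Il1r2 passed only with all mice or without saccharin day 16 replicate 2 or saccharin day 2 replicates 1, 4, 5 and 6 (otherwise 0.0533 to 0.289). Chil4 passed only with all mice or without saccharin day 16 replicates 1 and 2, saccharin day 2 replicate 1 or nicotine day 2 replicate 4 (otherwise 0.05 to 0.157).

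Camera called 27 lists in that difference. Proliferation lists had an adjusted p of 5.63e-19 (mitosis) and 1.74e-13 (DNA replication). Stress and metabolic lists had 3.67e-12 (inflammatory), 2.13e-05 (glutathione), 5.98e-05 (ribosomal proteins), 0.00207 (endoplasmic reticulum stress), 0.0116 (hypoxia) and 0.00645 (interferon-stimulated). Matrix and mesenchymal lists had 1.05e-05 (myofibroblasts), 0.000128 (elastic fibres), 0.000161 (collagens), 0.00125 (pericytes), 0.00226 (basement membrane), 0.00207 (mesothelium) and 0.0205 (hedgehog, FGF and PDGF). Epithelial and endothelial lists had 0.000161 (type 2 cells), 0.000883 (surfactant), 0.0113 (ciliated), 0.0271 (club) and 0.00645 (capillary). Blood and immune lists had 5.76e-07 (erythroid), 0.00145 (T and natural killer), 0.00207 (thymus), 0.00478 (neutrophils), 0.00776 (B cells), 0.0253 (MHC class II) and 0.0321 (monocytes). None passed with an estimated correlation, where the smallest adjusted p was 0.109. Without nicotine day 16 replicate 3 the ciliated (0.096), club (0.239), neutrophil (0.239), MHC class II (0.223), interferon-stimulated (0.0732), monocyte (0.0649) and hedgehog lists (0.163) no longer passed. The club list was also lost without saccharin day 16 replicate 4 (0.0871) or nicotine day 2 replicate 4 (0.105). MHC class II was lost without saccharin day 16 replicates 3 or 4 or nicotine day 2 replicate 2 (0.0543, 0.0506 and 0.0522). Monocytes were lost without saccharin day 16 replicates 1 or 4, nicotine day 16 replicate 1, saccharin day 2 replicates 1 or 2, or nicotine day 2 replicates 4 or 5 (0.0506 to 0.0814).

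The first pattern weighed was the higher mitosis and lower inflammatory genes of nicotine mice at day 2. Correcting each library for gene length and GC content left the medians at 2 and -3.95, with all 25 and all 24 members past the threshold, which argues against that trend as the whole cause. Without saccharin replicates 2, 3 and 6, chosen after their values were seen, the medians were 1.77 and -1.93, with 25 of 25 and 21 of 23 members passing, so those libraries do not account for the direction. With counts summed per block of consecutive mouse numbers, 34 of 49 genes passed, but each agent had 2 blocks, so a litter or a shared day cannot be told apart from nicotine. Nicotine exposure itself is among the explanations left open.

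The companion changes at day 2 differed under the same correction. After it 18 collagen and 15 elastic fibre genes, 33 together, were higher past the threshold, against 18 and 13 before, which argues against the length trend as their whole cause. The ribosomal median was -0.15 with 8 of 39 genes lower, so for these genes the trend and nicotine cannot be told apart. The correction can also remove biology that follows gene length, and only 1 version of it was run.

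The second pattern was the Y-linked transcripts of nicotine day 16 replicate 2, labelled female. Its 112 CPM lay within the day 16 males, whose lowest had 106, so male RNA mixed into a female library in a small share would have to reach the full male level. There were 0 libraries labelled male without these transcripts, which argues against a swap within the series. Kdm6a, which escapes X inactivation, was 30.8 CPM, within the day 16 males (27.1 to 41.8) and below the other females of that age (50.1 to 66.8), as was Eif2s3x (5.94, against 4.33 to 7.16 and 8.02 to 9.8). Kdm5c, at 103, lay within both (61.1 to 110 and 95.8 to 155) and does not separate the sexes. These values are consistent with a single wrong sex label, found and tested on the same data.

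Other splits of the same mice into groups of the same sizes were compared with the real ones. At day 2, 1 of 100 splits, the real one, gave as many as 6223 genes, and the highest other gave 2131. These splits treat mice as independent, so chance can be excluded only for an assignment of single mice. Day 2 mice came in 4 blocks of consecutive numbers with a within-block correlation of 0.257, and 3 splits of these sizes keep blocks whole, too few for a share under 0.05. Those gave the real 6223 and a highest other of 3. With blocks as a random effect in limma-voom 3230 genes passed, and 1528 with block sums. The difference between the ages gave 1 of 100 with 874 genes (highest other 0), development 1 of 100 with 6486 (highest other 4532) and sex 1 of 100 with 4 (highest other 0). Splits for the difference redrew the agent at both ages, which also removed the day 2 effect. They therefore cannot tell whether the effects at the ages differ. The difference and development splits ignore blocks too, and with random-effect blocks in limma-voom 2 and 4116 genes passed. With block sums 2309 genes passed for development. For the difference the nicotine day 16 mice form only 1 block, so a low count there does not show that the effects were alike. At day 16 the real count was 0, so all 56 splits had to give at least as many, which decides nothing. The highest other gave 17. For called lists chance cannot be excluded. As many lists came from 20 of 100 splits at day 2 (real 28, highest other 33), 12 of 56 at day 16 (19 and 30), 10 of 100 for the difference (27 and 33), 11 of 100 for development (22 and 29) and 14 of 100 for sex (24 and 32).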

How the results depend on the processing

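The length and GC correction, the mouse-number blocks, the changed sex label and the removals of 2, 3 or 4 libraries were chosen after the data had been seen. Named genes kept their call in 1722 of the comparisons with other settings, lost it in 187, gained it in 21 and changed sign in 16. Leaving out a mouse gave 1762, 118, 11 and 6. A change of sign counts only where the main or the alternative value passed. Lists kept their call in 2748, lost it in 280 and gained it in 86, and the direction camera gives changed in 13. Counts of genes or lists stayed within 1.5 times in 108 and moved further in 39. No paired analysis was possible because the labels give no replicate numbers, and those used here only name mice. Without a sex term the sex comparison has no value. The cause was not tested for any change below unless named.

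At day 2 the 6223 genes became 1650 with a 2-fold minimum, 1064 in the first number run only (4412 in the second, and 6714 with a term for the run) and 3818 in females only, which hold fewer mice. In the second run every nicotine mouse was male and every saccharin mouse female, so agent and sex cannot be told apart there. Nicotine females were all of the first run and most saccharin females of the second, so run and agent are largely confounded among females. The 6223 genes became 3230 with blocks as a random effect in limma-voom, 1528 with block sums and 3755 without 3 unusual saccharin libraries. The correction for length and GC gave 6297, of which 4377 were shared. At day 16 the 0 genes became 2 with RLE scaling, 12 with DESeq2, 2 with limma-voom, 1 with a CPM above 1 in at least 3 libraries, 3 with no sex term and 4 at an adjusted p under 0.1. They became 2 with the length and GC correction and 2 with the changed sex label. The 874 genes of the difference became 1754 with DESeq2, 3151 with limma-voom, 1942 at an adjusted p under 0.1 and 530 with a 2-fold minimum. They became 2 with random-effect blocks in limma-voom, where the nicotine day 16 mice form 1 block, and 1350 with the changed sex label. They were 93 without saccharin day 2 replicates 2 and 3 and nicotine day 2 replicate 3, 2379 without 4 of the strongest length trend and 410 without 3 unusual ones. Development went from 6486 to 2138 with a 2-fold minimum, 4116 with random-effect blocks and 2309 with block sums. Sex went from 4 to 10 with DESeq2 and 32 with limma-voom.

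Leaving out each mouse gave 5054 to 6690 genes at day 2, 0 to 7 at day 16, 3 to 2109 for the difference, 5269 to 6828 for development and 4 to 4 for sex. At day 16 nicotine replicates 3 and 2 gave 7 and 5, saccharin replicates 1 and 2 gave 1 each, and saccharin day 2 replicate 6 gave 2. For the difference the 3 came without nicotine day 16 replicate 3, with 453 and 343 without replicates 1 and 2. It was 1312, 245 and 525 without saccharin day 16 replicates 2, 3 and 5, and 2109 and 553 without saccharin day 2 replicates 1 and 2. It was 458, 249, 434 and 575 without nicotine day 2 replicates 1, 2, 3 and 5. For lists it gave 28 to 32, 8 to 22, 20 to 32, 20 to 27 and 16 to 29 in the same order, with the 8 reached without nicotine day 16 replicate 1. With an estimated correlation 0 lists passed in each of the 5 comparisons. Fry called 32 at day 2, 0 at day 16, 11 for the difference, 30 for development and 0 for sex. The correction for length and GC left 8 lists at day 16, and leaving out 4 libraries of the strongest length trend left 10.

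Muscle genes at day 2 had log2 fold changes below 0 without nicotine replicate 3, at -0.68 (Car3), -1 (Myh8), -1.94 (Atp2a1), -2.08 (Mylpf), -0.48 (Ryr1) and -0.07 (Neb). The highest values on leaving out a mouse were 4.98, 6.26, 6.12, 5.2, 3.89 and 4.07 in the same order. In the second number run only, which lacks that mouse, they were -0.16, -2.53, -3.04, -2.8, -1.3 and -0.54. Without saccharin day 2 replicates 2 and 3 and nicotine day 2 replicate 3, which keeps saccharin replicate 6, they were -0.29, -1.56, -2.51, -2.54, -0.66 and -0.58, and Xirp2 was -0.17. For Myh8, Atp2a1 and Mylpf saccharin replicate 6, with 23.8, 18.6 and 55.5 CPM, was the highest saccharin mouse of day 2. Without it and nicotine replicate 3 the values were -0.72, 0.84, -0.16, -0.68, 0.03 and 0.62 in the order above, so the signs of Myh8, Ryr1 and Neb depended on that mouse.

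The direction that camera gives, which sets a list against all other genes, changed under the length and GC correction for the lists below, with camera adjusted p. At day 2 these were oxidative phosphorylation (0.00141), ribosomal proteins (0.0858) and endoplasmic reticulum stress (0.644). At day 16 they were basement membrane (0.14), oxidative phosphorylation (0.011) and ribosomal proteins (0.0031), and for the difference oxidative phosphorylation (0.03) and ribosomal proteins (0.531). Their median log2 fold changes kept their sign except for oxidative phosphorylation, which went from -0.31 to 0.04 at day 2 and from 0.18 to -0.04 for the difference. Without 4 libraries of the strongest length trend, camera's direction at day 16 changed for the capillary (0.0254), basement membrane (0.291), oxidative phosphorylation (0.096), ribosomal (1.21e-11) and angiogenesis (0.289) lists. Depth limited genes near 0 CPM, such as Chrna3 and Chrna5. With the day 16 group sizes 55% of simulated 2-fold and 95% of 4-fold changes were recovered, in simulations simpler than the real data.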

Other observations

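The tests of the type 2 gene set, of the inflammatory genes in development and of the mitosis and inflammatory scores were chosen after their results were seen, and the length and GC correction was added after the data had been seen. Several lists of lung cells moved with age in saccharin mice beyond those described above. Of 16 alveolar macrophage genes 8 were higher and 3 lower at day 16 (camera adjusted p = 0.00893, adjusted p = 0.357 with an estimated correlation). Of 20 xenobiotic metabolism genes 11 were higher and 6 lower, with Fmo1, a flavin monooxygenase, at 471 against 137 CPM (camera adjusted p = 0.0201, adjusted p = 0.381 with an estimated correlation). That list did not pass without saccharin day 2 replicate 2 (0.0548), without saccharin day 2 replicates 2 and 3 and nicotine day 2 replicate 3 (0.113), without 4 of the strongest length trend (0.156) or without saccharin day 2 replicates 2, 3 and 6 (0.0625). Of 22 cholesterol synthesis genes 10 were lower and 0 higher, with Sqle, an early enzyme of the sterol branch, at 25.7 against 59.7 CPM (camera adjusted p = 0.00253, adjusted p = 0.353 with an estimated correlation). Crabp1, which binds retinoic acid, averaged 36.2 against 0.809 CPM, and 9 of 16 retinoic acid genes were higher and 3 lower (camera adjusted p = 0.0393, adjusted p = 0.353 with an estimated correlation). That list did not pass without saccharin day 16 replicate 2 (0.0556), without saccharin day 2 replicate 6 (0.0694), without that mouse and nicotine day 2 replicate 3 (0.0772) or after the length and GC correction (0.332).

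Between the sexes, lists of other tissues were higher in females without a passing member over all genes. Fat genes had a median log2 difference of 0.91 and upper airway and cartilage genes 0.74, each with a camera adjusted p = 3.91e-07 and an adjusted p = 0.24 with an estimated correlation. In each of these lists 3 genes passed when adjusted over the list alone. Nicotine day 2 replicate 3, which had the highest muscle and fat scores of its group, is labelled female.

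Of the 28 lists that camera did not call at day 2, monocytes and interstitial macrophages lay closest, with 1 higher and 6 lower of 16 genes (adjusted p = 0.0508). That list passed without saccharin day 16 replicate 1, nicotine day 2 replicates 1, 2 or 3 or saccharin day 2 replicates 3, 4 or 5 (0.0207 to 0.0482). Matrix metalloproteinase genes went both ways, with 8 higher and 8 lower of 21 (adjusted p = 0.633), as did lipofibroblast genes, with 8 and 5 of 18 (0.238). Xenobiotic metabolism genes were higher in 2 and lower in 8 of 20 cases (0.0647) and interferon-stimulated genes in 2 and 7 of 26 (0.0777).

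A candidate explanation for the day 2 difference is delayed maturation of nicotine lungs, in which genes that rise with age would be lower at day 2 in nicotine mice. The covariance across genes of the nicotine effect at day 2 with the change from day 2 to day 16 was 0.2 with shared controls, against 0.03 in simulations. With the 6 saccharin day 2 mice split between both contrasts it was 0.155 (0.0759 to 0.221 over 20 splits), against 0.00051 simulated, and 0.153 after the length and GC correction. Delay alone needs a value below 0, so it is argued against as the whole cause. A state shared by all saccharin day 2 mice would add to both contrasts and survive the split, and a delay hidden under such a state stays open. That 22 of 24 inflammatory genes were lower in both contrasts decides nothing, because both subtract the same saccharin day 2 mice.

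Of the genes higher in nicotine mice at day 2, 1069 were higher and 409 lower at day 16 than at day 2, against 603.4 and 655.8 for independent lists. Of those lower in nicotine mice, 283 were higher and 1095 lower, against 673.8 and 732.3, and these overlaps share the saccharin day 2 mice. The correlation r of the same contrasts across genes was 0.351 with shared controls (simulated 0.46) and 0.263 with split controls (simulated 0.0055). The simulations held no age or nicotine effect, so their r with shared controls is that of noise alone and cannot be ranked against the real r. The mean log2 CPM of the inflammatory list was 5.54 ± 1.54 (SD, n = 6) in saccharin day 2 mice, 2.49 ± 0.37 (n = 5) in nicotine day 2 mice and 2.05 ± 0.14 (n = 5) in saccharin day 16 mice. For mitosis the values were 3.22 ± 0.95, 5.4 ± 0.26 and 2.98 ± 0.29.

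At day 16, goblet cell genes chosen after their values were seen were lower in nicotine mice without passing. They included Clca1 at 44.1 ± 16.8 against 258 ± 130 CPM (edgeR adjusted p = 0.317) and Muc5ac at 3.54 against 10. A second set of type 2 response genes, of which 20 of 26 could be tested, had a mean log2 CPM of 0.91 ± 0.11 (SD, n = 3) against 1.36 ± 0.17 (n = 5), with an exact two-sided permutation p = 0.0357. That test treats mice as independent, while the 3 nicotine mice form 1 block of consecutive numbers, so a litter or shared day cannot be told apart from nicotine here. The set was written down after the goblet genes had been seen, and 2 of its genes stood in lists already displayed.

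Nicotine effects at both ages correlated across genes with a Spearman rho of 0.266, and 0.158 after the length and GC correction. Leaving out each mouse moved the corrected value from 0.062 to 0.254, so whether the trend accounts for most of it cannot be told. After the correction 14 of 56 splits of the day 16 mice gave as large a rho, with a highest other of 0.423, so chance cannot be excluded.

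Among the 6 saccharin day 2 mice the mitosis score ran against the inflammatory score with a Pearson r of -0.699 (exact permutation p = 0.112) and a Spearman rho of -0.6 (exact permutation p = 0.242). Without replicates 6 and 1, the farthest from the median, r was 0.569, so the relation rests on those mice. It was the only relation of its kind computed, and each number run holds 3 of these mice, too few for a value.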
